A study of Mus musculus with 6 samples.

How the data were processed

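RNA was sequenced from T helper 17 (Th17) cells differentiated in culture from wild-type (WT) C57BL/6 mice and from mice lacking GOT1 in T cells (GOT1-/-), with 3 libraries per genotype. Per the labels' protocols, naive CD4 T cells were sorted from mice aged 6 to 10 weeks of either sex, and T cells were activated with anti-CD3 at 5 ug/ml and anti-CD28 at 2 ug/ml. The Th17 medium held TGF-beta at 2.5 ng/ml, IL-1beta, IL-6 and IL-23 at 10 ng/ml each, and antibodies against IFN-gamma and IL-4 at 2 ug/ml each. Fresh medium was given on day 2 and RNA was taken on day 4. Libraries were made from 1 ug of RNA by poly-A selection with a NEBNext Ultra RNA kit, which the labels do not describe as strand-specific. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

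The authors deposited whole-number read counts per gene, not normalized, for 54532 genes. Per the submitters' processing notes, STAR and the mouse genome build GRCm38 were used. The version of STAR, the counting tool, its strand setting and the annotation are not given in the sources used here. Reads shared between paralogs, overlapping genes or antisense partners may therefore be divided between them in ways that cannot be checked here. Of the deposited gene IDs, 54495 were found in GENCODE mouse release M21, also on GRCm38, and 98.3% of these had the same chromosome, start and end. Coordinates and gene lengths are those of the deposited table. The length given there for Got1, 2539 bp, is well under the span of its coordinates. Gene length here is therefore not the genomic span. Symbols of 27 genes had been turned into dates there, and all 27 were restored from their gene IDs. Where 103 symbols were repeated, the copy with the most reads kept the symbol.

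Library totals ranged from 16463752 to 22541410 counts. A count of 3 corresponded to 0.133 to 0.182 CPM (counts scaled to 1000000 per library). This was taken as the limit that a count of 0 allows, covering counting error only. Libraries of the same genotype differed by more than sampling noise (chi-square per degree of freedom of 3.76 to 13.7 over genes with a summed count of at least 20), so all 6 libraries were kept as separate samples. CPM values were computed on library sizes scaled by the trimmed mean of M-values (TMM), with factors between 0.976 and 1.01.

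Genotypes were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 12873 genes. The quasi-likelihood F-test was two-sided, had genotype as its only term, and was adjusted by the Benjamini-Hochberg method over all genes tested, with calls made at an adjusted p under 0.05. All adjusted p-values of single genes come from this test. Before the data were examined, 38 gene lists were fixed, besides Got1 itself, and the 37 with at least 3 tested members were tested as groups with camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Members of each list were also counted with p-values adjusted over the list alone. Named genes followed a rule fixed at the same time: Got1, the 8 protein-coding genes with the largest called change in each direction among those with a mean of at least 2 CPM and no overlap between genotypes, leaving out immunoglobulin and T cell receptor segments, 13 genes chosen in advance, and up to 4 called members of each list with the smallest adjusted p. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

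Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, other scalings, filters and thresholds, a robust dispersion, protein-coding genes only, chromosomes X and Y left out, the replicate number as a block, an estimated correlation or a prior count of 0.5 in camera, and each library left out in turn. With an estimated correlation camera also rests on the residual degrees of freedom of these few libraries. It can then call few lists, so a call lost in that setting is not evidence against a list. After the data were seen, corrections were added that removed each library's smooth trend over gene length, or over length and GC content, fitted by robust regression on natural splines with 5 degrees of freedom. The procedure was tested on simulated data for the comparison of GOT1-/- with WT. Over 12716 genes, edgeR recovered 41.7% of genes changed 1.3-fold, 67.3% of those changed 1.5-fold, 80% of those changed 2-fold and all 50 of those changed 4-fold, and it called 8 unchanged genes. When the observed length trends were also put into simulated counts of 12734 genes, edgeR called 946 unchanged genes, or 7.55%, and 6 with the length correction.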

Results

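The comparison of GOT1-/- with WT Th17 cells asks how loss of GOT1, the cytosolic aspartate transaminase of the malate-aspartate shuttle, changes the transcripts of cells made under Th17 conditions. Expression was measured by poly-A RNA sequencing in 3 WT and 3 GOT1-/- libraries, whose total counts were 19623164, 21239075 and 16463752 for WT and 20646004, 22541410 and 17557436 for GOT1-/- replicates 1 to 3. Got1 itself (ENSMUSG00000025190, chromosome 19, 43499752 to 43524605 on GRCm38, minus strand) had 3284, 3524 and 2873 counts in WT replicates 1 to 3 and 332, 339 and 300 in GOT1-/- replicates 1 to 3. Its level was 168 ± 4.59 CPM in WT and 16.2 ± 1.25 CPM in GOT1-/- cells (SD, n = 3 each), a 10.4-fold decrease (log2 fold change -3.38, SE 0.08, adjusted p = 2.15e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The part of the gene that was deleted is not given in the sources used here.

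Of the genes measured, 55 of 69 nuclear-encoded respiratory chain subunits, 27 of 32 amino acid response genes and 14 of 20 glycolysis genes rose in GOT1-/- cells, whereas 11 of 13 mitochondrially encoded genes and 9 of 11 markers of naive and memory T cells fell. Each of these lists was called by camera with a preset correlation, and each had an adjusted p = 0.348 with an estimated correlation. The Th17 genes themselves moved in both directions, with higher Il17a and Il22 and lower Ahr, Maf and Il23r. In all, 5643 of 12873 genes were called, or 43.8%, of which 2944 were higher and 2699 lower in GOT1-/- cells. Most changes were small: 545 called genes changed at least 2-fold, 313 upwards and 232 downwards. The levels of all 3 GOT1-/- libraries lay on one side of all 3 WT libraries for 53.4% of genes, where chance gives 10%.

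The fold changes followed gene length, as deposited and not the genomic span, and GC content. Among 11526 protein-coding genes, Spearman's rho between length and log2 fold change was -0.397, a correlation across genes, which are not independent replicates. With GC content it was 0.311. The libraries of each genotype shared the length trend: rho between length and a library's deviation from the mean of all libraries was 0.342, 0.287 and 0.38 in WT and -0.172, -0.345 and -0.446 in GOT1-/- replicates 1 to 3. Of 10 equal bins by length, the bin of the shortest genes had a median log2 fold change of 0.29, with 46.8% of genes higher and 6.4% lower. In the bin of the longest genes it was -0.29, with 6.5% higher and 52.1% lower. After a correction for length, chosen after the data were seen, 5236 genes were called, and 4307 of the calls were shared with the uncorrected comparison in the same direction. After a correction for both length and GC content, chosen at the same time, 5357 genes were called and 4148 shared in the same direction.

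Among protein-coding genes other than Got1 with a mean of at least 2 CPM and no overlap between genotypes, Capn11, a calpain protease gene, had the largest increase, from 0.117 ± 0.163 to 3.89 ± 0.744 CPM (log2 fold change 4.93, adjusted p = 5.50e-07). Capn11 had 6, 1 and 0 counts in WT replicates 1 to 3, so the size of its change is uncertain. Gzmc, which encodes a granzyme of cytotoxic granules, rose from 1.01 ± 0.186 to 8.85 ± 1.48 CPM (3.14 on the log2 scale). Shroom3 (2.81), Mapkapk5 (2.69), the chemokine gene Ccl22 (2.53), Nov (2.48), Il22 (2.28) and the type 2 cytokine gene Il13 (2.21) followed in log2 fold change, all at WT levels under 4 CPM. Among the same genes the largest decreases were those of Serpinb5, a serpin gene, from 88.5 ± 10.1 to 16.7 ± 2.16 CPM (log2 fold change -2.41, adjusted p = 1.46e-10), and of Dnm3 (-2.36). Ly6g fell from 152 ± 4.21 to 31.8 ± 7.45 CPM (-2.26) and belongs to a family of similar genes among which reads may be divided. Epb41l4b (-1.93), Hey1 (-1.90), Ppp1r3c (-1.88), Prg4 (-1.84) and the interleukin 1 receptor gene Il1r1 (-1.75) completed the group in log2 fold change. Prg4 overlaps Tpr on the opposite strand, so its counts are uncertain. The counts of Mapkapk5 are uncertain too, since it overlaps other genes on its own strand, among them Adam1a.

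The Th17 programme split. Of its 20 measured genes, 8 rose, 7 fell and 5 were not called, with the same 8 and 7 when adjusted over the list alone. Il17a rose from 75.6 ± 0.736 to 123 ± 10.2 CPM (log2 fold change 0.70, SE 0.08, adjusted p = 2.17e-06), and Il22 rose from 3.87 ± 0.679 to 18.6 ± 0.3 CPM (2.28, SE 0.13, adjusted p = 3.21e-09). Outside this list, the gamma-delta T cell receptor genes Trdc and Tcrg-C2 rose, from 3.73 ± 0.659 to 6.78 ± 0.8 CPM and from 1.63 ± 0.426 to 3.38 ± 0.632 CPM. Their own list, of CD8, NK and gamma-delta T cell markers, was not called (camera adjusted p = 0.12), and its member Klrd1 fell (-0.56). Whether such cells contributed to Il17a and Il22 was not tested. Il23r (-0.86, adjusted p = 0.000754), the aryl hydrocarbon receptor gene Ahr (-1.37, adjusted p = 1.08e-08) and the transcription factor gene Maf (-1.17, adjusted p = 1.51e-08) fell in log2 fold change. Il17f was at 1075 ± 52.8 CPM in WT and 1012 ± 50.2 CPM in GOT1-/- cells and was not called (adjusted p = 0.311). It was called lower after the length correction (-0.26, adjusted p = 0.0027) and the length and GC correction (-0.15, adjusted p = 0.0289; range over all alternatives 0.0027 to 0.549). As a group the list was not called by camera (adjusted p = 0.807).

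**Figure D1:**
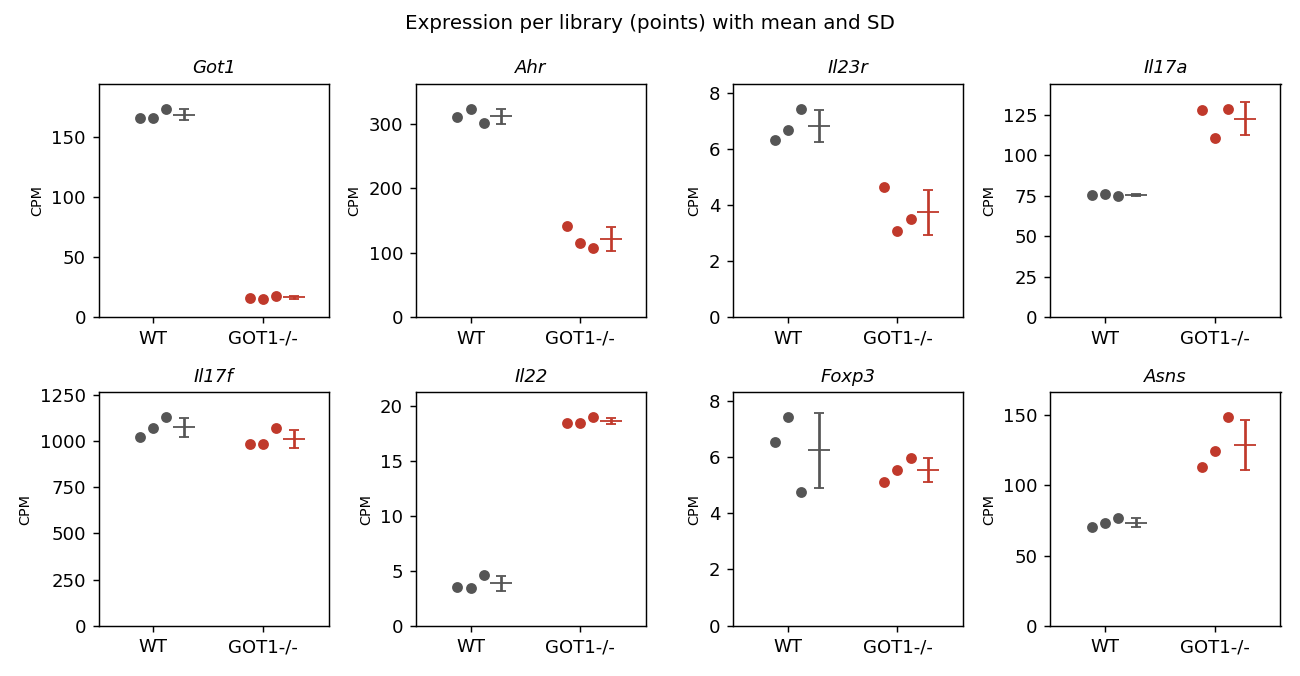
Expression in CPM (vertical axes, from 0) of 8 genes in WT and GOT1-/- Th17 cells; each point is a library, and the bar and whiskers give the mean and SD of 3 libraries. Got1, Ahr and Il23r were lower and Il17a, Il22 and Asns higher in every GOT1-/- library, whereas Il17f and Foxp3 were not called.

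Genes of other T cell states also differed. In the pathogenic Th17 list 5 of 13 genes rose and 2 fell, or 7 and 2 adjusted over the list alone. After the length correction 4 fell, and after the length and GC correction 2. The list was not called (camera adjusted p = 0.124). The cytotoxic protease gene Gzmb rose from 23.1 ± 1.72 to 83 ± 3.24 CPM and Ccl3 from 0.76 ± 0.179 to 2.55 ± 0.218 CPM. Stat4 fell from 41.9 ± 3.76 to 22.8 ± 2.17 CPM. Csf2 was at 4.52 ± 0.33 CPM in WT and 3.56 ± 0.818 CPM in GOT1-/- cells and was not called (adjusted p = 0.145). It was called lower after the length correction (log2 fold change -0.56, adjusted p = 0.0223) and without GOT1-/- replicate 3 (0.0361) but not after the length and GC correction (0.0517), with a range over all alternatives of 0.0223 to 0.364. Of 9 Th2 genes 5 rose and none fell, with the same counts adjusted over the list alone. The list was called higher (camera adjusted p = 0.00409; adjusted p = 0.348 with an estimated correlation). Il24 rose from 68.4 ± 2.75 to 235 ± 13.3 CPM, and the Th2 transcription factor gene Gata3 from 10.4 ± 0.819 to 13.9 ± 0.509 CPM. The members that were not called, named after their values were seen, were Il4 (adjusted p = 0.106), Ccr4, Ccr8 and Il4ra. Without WT replicate 3, 1 member of the list fell. The mast cell and basophil markers Prss34 and Gata2, from a list written after the data were first examined, rose by 2.50 and 2.26 on the log2 scale. Ifng rose from 0.456 ± 0.116 to 1.53 ± 0.24 CPM (log2 fold change 1.74, adjusted p = 0.000712). In the Th1 list 4 of 14 genes rose and 4 fell, or 5 and 4 adjusted over the list alone. Of 19 regulatory T cell genes 9 rose and 3 fell, or 10 and 3 adjusted over the list alone. The list was not called (camera adjusted p = 0.111). Foxp3 was at 6.24 ± 1.34 CPM in WT and 5.54 ± 0.421 CPM in GOT1-/- cells (adjusted p = 0.396), with a log2 fold change of -0.19 that was -0.04 without WT replicate 2 and -0.35 without WT replicate 3. Il10 was at 11.5 ± 1.48 and 12 ± 1.27 CPM (adjusted p = 0.701), and its log2 fold change of 0.07 turned to -0.02 without GOT1-/- replicate 1 and to -0.05 without WT replicate 1.

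Of 11 measured markers of naive and memory T cells 9 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 1.83e-05; adjusted p = 0.348 with an estimated correlation). The interleukin 7 receptor gene Il7r fell from 413 ± 33 to 156 ± 14.9 CPM and the transcription factor gene Tcf7 from 873 ± 17.3 to 429 ± 26.3 CPM. Of 11 follicular helper T cell (Tfh) genes 6 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.348 with an estimated correlation). Bcl6, the transcriptional regulator of that lineage, fell from 30.3 ± 3.36 to 10.4 ± 1.93 CPM and Pou2af1 from 24.1 ± 2.74 to 8.05 ± 1.06 CPM. The 2 that rose, chosen after their values were seen, were Sh2d1a (log2 fold change 0.66) and Cd200 (0.21), the latter not called after the length correction (adjusted p = 0.177) but called after the length and GC correction (0.0047). Without GOT1-/- replicate 2 or WT replicate 1, 1 member rose. This list was no longer called without GOT1-/- replicate 1 (adjusted p = 0.0895), WT replicate 2 (0.0692) or WT replicate 3 (0.104), and its adjusted p ranged from 0.00339 to 0.348 over all alternatives.

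Lists of amino acid metabolism differed in their calls. Of 32 genes of the ATF4 and amino acid response 27 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 1.42e-08; adjusted p = 0.348 with an estimated correlation). Phgdh, which encodes the entry enzyme of serine synthesis, rose from 148 ± 5.97 to 296 ± 34.7 CPM, and the amino acid transporter gene Slc7a5 from 279 ± 17.8 to 492 ± 19 CPM. Asns, which encodes asparagine synthetase, rose from 73.2 ± 3.22 to 129 ± 18.1 CPM (log2 fold change 0.81, adjusted p = 2.57e-06). Of 16 serine and one-carbon genes 11 rose and none fell, also when adjusted over the list alone, among them Psph (0.92) and Shmt2 (0.64) in log2 fold change (camera adjusted p = 0.000338; adjusted p = 0.348 with an estimated correlation). Psph overlaps Cct6a, with a mean of 5664 counts, on the opposite strand, so the counts of Psph are uncertain. In the malate-aspartate shuttle and transaminase list, which leaves out Got1, 8 of 14 genes rose and none fell, or 9 adjusted over the list alone (camera adjusted p = 0.00545; adjusted p = 0.378 with an estimated correlation). The members that rose included the transaminase genes Gpt2 (0.88), Psat1 (0.73) and Bcat2 (0.48). Of the enzymes nearest to GOT1, the mitochondrial transaminase gene Got2 was at 257 ± 4.58 CPM in WT and 278 ± 16.8 CPM in GOT1-/- cells (adjusted p = 0.187). Mdh1 was at 227 ± 3.75 and 250 ± 15.5 CPM (adjusted p = 0.107; 0.0348 without GOT1-/- replicate 1; range over all alternatives 0.0348 to 0.99). Among 14 genes of aspartate and asparagine use and uptake 5 rose and 2 fell, or 7 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.26). The aspartate and glutamate transporter gene Slc1a1 fell from 2.98 ± 0.306 to 0.835 ± 0.162 CPM. Without GOT1-/- replicate 2 or WT replicate 2, 1 gene of that list fell.

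Of 20 glycolysis genes 14 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000926; adjusted p = 0.348 with an estimated correlation). The hexokinase gene Hk2 rose from 81.3 ± 3.47 to 120 ± 7.16 CPM and the lactate dehydrogenase gene Ldha from 2265 ± 118 to 3220 ± 312 CPM (log2 fold change 0.51, adjusted p = 4.33e-05). The glucose transporter gene Slc2a1 rose from 171 ± 13.3 to 202 ± 15.3 CPM (0.24, adjusted p = 0.0189), a call that was lost after the length correction (adjusted p = 0.102), the length and GC correction (0.305) and without GOT1-/- replicate 2 (0.152) or WT replicate 2 (0.134), with a range over all alternatives of 0.00148 to 0.305. Of 24 TCA cycle genes 13 rose and none fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.348 with an estimated correlation). The list also holds genes next to the cycle, among them Pcx and Acly, which rose by 0.75 and 0.55 on the log2 scale. Acly is also in the list of fatty acid synthesis and oxidation. Of 13 genes of NADPH supply and the pentose phosphate pathway 6 rose and none fell, or 7 adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.348 with an estimated correlation). That call was lost after the length correction (adjusted p = 0.0948) but not after the length and GC correction (0.0462; range over all alternatives 0.00432 to 0.348).

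The respiratory chain was divided by the genome that encodes it. Of 69 nuclear genes for its subunits 55 rose, none fell and 14 were not called, or 56 rose adjusted over the list alone, with a median log2 fold change of 0.47 (camera adjusted p = 1.09e-12; adjusted p = 0.348 with an estimated correlation). Ndufa1, a subunit gene of complex I, rose from 16.6 ± 1.67 to 51.1 ± 5.88 CPM, and Atp5k, of the ATP synthase, from 6.29 ± 1.16 to 23.6 ± 2.89 CPM. These genes are short, with a median length of 1675 bp, and after the length correction 46 were higher and 5 lower. Of 13 mitochondrially encoded genes 11 fell and none rose, or 12 fell adjusted over the list alone, with a median log2 fold change of -0.54 (camera adjusted p = 0.000703; adjusted p = 0.348 with an estimated correlation). mt-Co1 fell from 9926 ± 724 to 6147 ± 104 CPM and mt-Nd5 from 1205 ± 223 to 649 ± 104 CPM. Mitochondrial transcripts made up 1.66, 1.56 and 1.88% of counts in the WT libraries and 1.14, 1.1 and 1.1% in the GOT1-/- libraries.

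**Figure D2:**
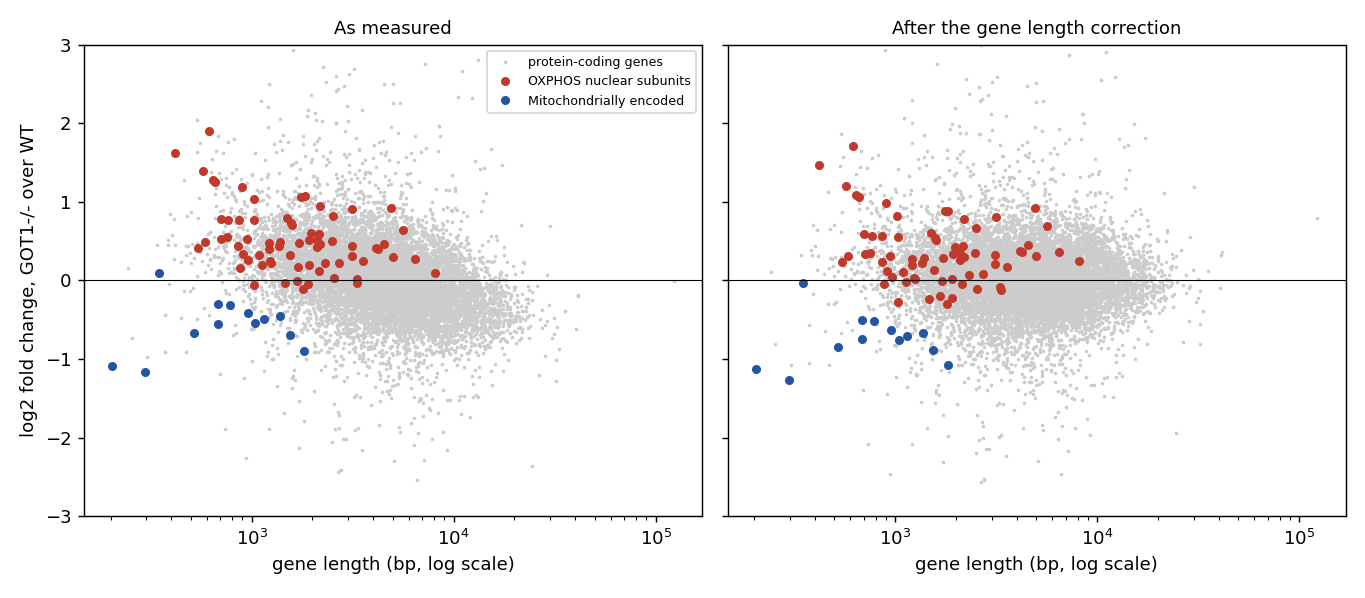
Log2 fold change of GOT1-/- over WT (vertical axis, drawn to 3 in either direction, leaving out 13 genes as measured and 12 after correction) against gene length in bp (log scale) for protein-coding genes, as measured and after the length correction. Nuclear genes of oxidative phosphorylation (OXPHOS; red, median 0.47 as measured and 0.31 corrected) lie above most genes of their length, and mitochondrially encoded genes (blue, -0.54 and -0.75) below.

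Of 26 cell cycle genes 18 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000103; adjusted p = 0.378 with an estimated correlation). Among its members Mcm5 rose from 99.7 ± 6.26 to 179 ± 15.7 CPM and Pcna from 179 ± 6.44 to 319 ± 34.9 CPM. The 2 that fell, chosen after their values were seen, were the proliferation marker gene Mki67 (log2 fold change -0.39) and Top2a (-0.24), and neither was called after the length correction (adjusted p = 0.124 and 0.518) or the length and GC correction (0.163 and 0.863). Of 20 nucleotide synthesis genes 13 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00465; adjusted p = 0.538 with an estimated correlation). Cad, which encodes the aspartate-using enzyme that opens pyrimidine synthesis, rose from 99.5 ± 3.54 to 160 ± 3.87 CPM. The 2 that fell, chosen after their values were seen, were Ctps2 and Adss, and without GOT1-/- replicate 2 or WT replicate 2 only 1 fell. Of 20 cholesterol synthesis genes 8 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.00358; adjusted p = 0.348 with an estimated correlation), including Lss (0.66) and Mvd (0.60, or 0.31 after the length and GC correction) in log2 fold change. Without GOT1-/- replicate 3, 1 gene of that list fell.

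Some markers of other cell types differed between genotypes. Of 10 macrophage, monocyte and neutrophil markers 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.348 with an estimated correlation). The call was lost under a stricter filter on low counts (adjusted p = 0.0579; range over all alternatives 0.00115 to 0.348), under which 4 members rose. Lyz2 rose from 4.03 ± 0.77 to 12.6 ± 1.69 CPM and the neutrophil protein gene S100a8 from 2, 1 and 3 counts in the WT libraries to 27, 28 and 17 in the GOT1-/- libraries. Cd68 fell from 19.6 ± 2.08 to 11.1 ± 1.18 CPM. Of 6 dendritic cell markers 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0544; adjusted p = 0.348 with an estimated correlation). The list was called without WT replicate 2 (0.0355) or GOT1-/- replicate 3 (0.0495), with limma-voom (0.0324), the replicate block (0.0436), a stricter filter (0.0107) or no filter (0.00836). After the length correction, and after the length and GC correction, 3 members were higher. H2-Ab1, at 102 ± 16.4 CPM in WT and 125 ± 5.94 CPM in GOT1-/- cells with overlapping libraries, was then not called (adjusted p = 0.402 and 0.924), nor was it without GOT1-/- replicate 2 (0.0782), WT replicate 1 (0.0714) or WT replicate 3 (0.138). Of 8 markers of CD8, NK and gamma-delta T cells 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.12). Of 5 B cell markers 2 fell, Ighm and Igkc, and none rose, also when adjusted over the list alone (camera adjusted p = 0.26). Xist was detected at 3778, 3768 and 3722 counts in WT and 3633, 2586 and 1550 counts in GOT1-/- replicates 1 to 3 (adjusted p = 0.00353; 0.0779 with DESeq2), with a log2 fold change of -0.64, or -0.30 after the length correction (adjusted p = 0.0376) and -0.23 after the length and GC correction (0.0919). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 6 libraries.

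**Figure D3:**
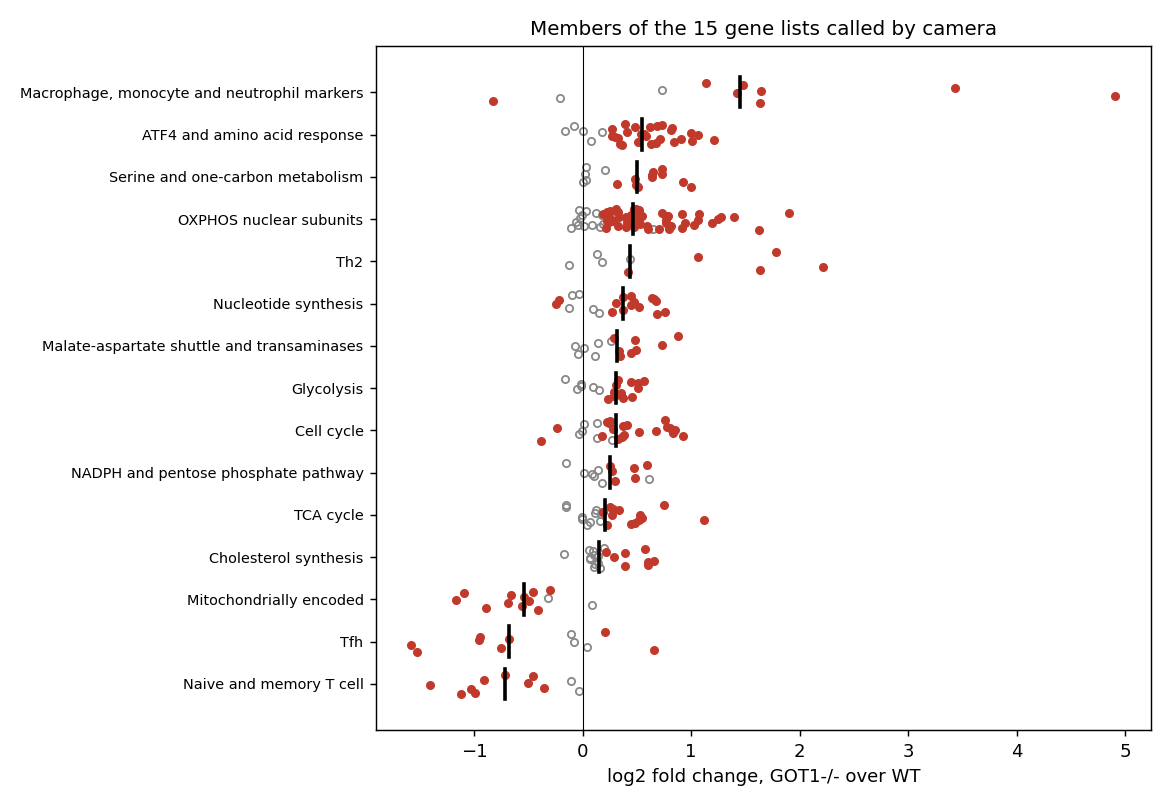
Log2 fold change of GOT1-/- over WT (horizontal axis) of every measured member of the 15 gene lists called by camera with a preset correlation. Filled points are called genes, open points genes that were not called, and the black bar is the list's median, which ranged from -0.71 for naive and memory T cell genes to 1.45 for macrophage, monocyte and neutrophil markers.

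Of the 37 lists tested, 12 were called higher and 3 lower by camera, and the remaining lists were not called. With an estimated correlation 0 of the 15 calls held. For the macrophage, monocyte and neutrophil list this loss does not follow from correlation alone. That list had an estimated correlation of -0.032, below the preset 0.01, and its adjusted p by camera still went from 0.016 to 0.348. The other called lists had estimated correlations from 0.058 (cholesterol synthesis) to 0.452 (nucleotide synthesis), all above the preset value. Their adjusted p with the preset correlation may therefore be too small. Among hypoxia and HIF1 targets 7 of 21 genes rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.424), with Higd1a higher and Hif1a itself lower (log2 fold change -0.41, or -0.24 after the length and GC correction). In glutamine and glutamate metabolism 7 of 16 rose and 2 fell, or 7 and 3 adjusted over the list alone (0.124). Of 13 interferon-stimulated genes 5 rose and 3 fell, also when adjusted over the list alone (0.807), and Gbp2 fell by 1.23 while Usp18 rose by 1.26 on the log2 scale. Without GOT1-/- replicate 3, 5 of that list fell, and after the length and GC correction 3 were higher and 4 lower. Of 17 genes of fatty acid synthesis and oxidation 3 rose and 3 fell, also when adjusted over the list alone (0.625). In that list 8 were higher after the length correction, 7 after the length and GC correction and 6 without GOT1-/- replicate 3. In the list around 2-hydroxyglutarate and DNA and histone methylation 4 of 19 genes rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.409). Without GOT1-/- replicate 2, 1 rose, and without WT replicate 2, 2 rose. Uhrf1 rose by 0.65 on the log2 scale. The histone demethylase genes Kdm5b and Kdm6a, which are long, fell by 0.58 and 0.61, by 0.24 and 0.45 after the length correction, and by 0.25 and 0.37 after the length and GC correction. Glutamine and glutamate metabolism was called higher after the length correction (camera adjusted p = 0.0307) and the length and GC correction (0.0322; adjusted p = 0.348 with an estimated correlation and no length correction). The STAT3 and IL-6 response was called lower after it (0.0928 before and 0.0307 after, or 0.0043 after the length and GC correction; 0.0436 without WT replicate 3; adjusted p = 0.538 with an estimated correlation and no length correction). In this list 2 of 12 genes rose and 6 fell, also when adjusted over the list alone, and Bcl6, Il6st and Socs3 were among those that fell.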

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

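The corrections for gene length and GC content were chosen after the data were seen; the other alternatives were fixed before. The count of 5643 called genes stayed between 4008 (adjusted p under 0.01) and 5792 (replicate block) over all alternatives but the 2-fold threshold, which left 545 genes, 313 higher and 232 lower; a threshold on size leaves fewer genes by construction. Leaving out each library in turn gave 4426 to 5718. The Got1 log2 fold change stayed between -3.438 and -3.3369 when a library was left out and between -3.5512 and -3.3478 otherwise. Of the 15 lists called by camera, 0 were called with an estimated correlation, where 3 lists had an unadjusted p under 0.05, whereas fry, which tests whether a list's genes move one way without comparing it with other genes, called 30 of 37. Without a filter on low counts camera called 22. Upper-quartile scaling raised the share of calls that were higher from 52.2% to 57.2%. The labels give the replicates no pairing. Same-numbered deviations from the genotype mean correlated at 0.059, -0.026 and 0.033, and 3 of 6 libraries correlated best with their own number. A principal component with 11.6% of the variance, however, placed replicates 1 to 3 alike in WT (13.1, 3.2 and -17.5) and GOT1-/- cells (11.2, 4.3 and -14.2), and total counts ranked alike, so an effect shared by number stays open. With the number as a block, 5792 genes were called, 5574 of them shared with the unblocked comparison. Of 147 called named genes other than Got1, 138 kept their call and direction in each of the 18 settings that tested them. Some genes were not tested in every setting, such as Ighm with protein-coding genes only. Directions reversed, each without a call, in these cases, and the cause was not tested. Il10 had a log2 fold change of -0.136 with the length and -0.022 with the length and GC correction, and between -0.0459 and 0.1523 when a library was left out. Lag3 came to -0.0132 with the length and GC correction and Mdh1 to -0.0013 with the length correction. Among lists, camera's direction turned with the length correction for 2-hydroxyglutarate (adjusted p = 0.861) and immediate-early genes (0.798), with length and GC for immediate-early genes (0.501) and Th1 (0.922), for B cell markers with protein-coding genes only (0.674), for erythroid and stromal markers without a filter (0.948) and with the replicate block (0.98), without GOT1-/- replicate 2 for erythroid and stromal markers (0.596 to 0.946 over libraries left out), and without GOT1-/- replicate 1 for interferon-stimulated genes (0.591 to 0.995). Depth limits genes below about 0.182 CPM, the level of 3 counts in the smallest library.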

Other observations

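Of the tests in this part, those of gene length and GC content, of marker lists without their dominant gene, and of ribosomal and proteasome gene families were chosen only after the result was seen. Several fixed lists held changes in both directions without a call by camera. Among 16 genes of p53 targets and apoptosis 6 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.534): the proapoptotic gene Bcl2l11 fell by 1.29 and Trp53inp1 by 1.15, while the antiapoptotic gene Bcl2l1 rose by 0.54 on the log2 scale. Of 16 chemokine and homing receptor genes 4 rose and 7 fell, also when adjusted over the list alone (0.209), with Ccl22 higher and S1pr1 lower. Of 12 TGF-beta response genes 2 rose and 6 fell, or 3 and 7 adjusted over the list alone (0.185): Smad3 (-0.58) and Ski (-0.47) fell, and Pmepa1 (0.59) rose. Of 16 NRF2 targets 7 rose and 2 fell, or 8 and 4 adjusted over the list alone (0.12), with the thioredoxin gene Txn1 (0.82) and Srxn1 (1.11) among those that rose; none fell without GOT1-/- replicate 1 or WT replicate 2, and 5 fell after the length correction, as after the length and GC correction. Of 17 activation and inhibitory receptor genes 2 rose and 3 fell, or 2 and 2 adjusted over the list alone (0.669), including Tnfrsf9 (0.66) and Myc (-0.37), and 1 rose without WT replicate 3. After the length and GC correction 2 of these genes were higher and 6 lower. Of 9 non-pathogenic Th17 genes 1 rose, Il9 (2.04), and 4 fell, also when adjusted over the list alone (0.26). Of 12 immediate-early and heat shock genes, a sign of handling, 3 rose and 2 fell, or 4 and 3 adjusted over the list alone (0.8), and 5 rose without GOT1-/- replicate 1. In the same list 2 were higher and 4 lower after the length and GC correction. Of 3 erythroid and stromal markers 1 fell, Pecam1 (-0.31), also when adjusted over the list alone (0.835), a call that was lost without GOT1-/- replicate 2 (adjusted p = 0.0565) or WT replicate 2 (0.0605).

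Families were also picked by symbol after the values were seen. Of 77 mitochondrial ribosomal protein genes 50 rose and 1 fell (median log2 fold change 0.32), or 36 and 1 after the length correction; 2 fell without GOT1-/- replicate 3. Of 37 proteasome subunit genes 25 rose and none fell (0.30), or 21 and none after the length correction; 1 fell without GOT1-/- replicate 3. Of 76 cytosolic ribosomal protein genes 41 rose and 2 fell (0.23), but 25 were higher and 12 lower after the length correction (0.07) and 29 and 12 after the length and GC correction. Leaving out a library changed the number that fell to 8 without GOT1-/- replicate 3, 1 without GOT1-/- replicate 1 or 2, and none without WT replicate 1 or 2. Reads of this family can be shared with pseudogenes. With the length correction, camera gave an adjusted p over these 3 families of 2e-06, 1.19e-05 and 0.06, with the length and GC correction 2.06e-07, 6.38e-07 and 0.0273, and 0.316 for each with an estimated correlation and no length correction.

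Gm42031 is a long noncoding RNA gene on chromosome 8 (85125872 to 85132289 on GRCm38), chosen after its values were seen. It had 0 counts in every WT library and 210, 306 and 234 in the GOT1-/- libraries. Its level was at least 236-fold higher against a floor of 3 counts over the WT group. Whether this follows from loss of GOT1 or from another difference between the mice was not tested.

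The number of called genes was set against the other ways of dividing the 6 libraries into groups of 3. Of 10 splits, 1, the real one, called as many as 5643 genes, and the highest of the others called 0 by edgeR, with at most 294 genes at an unadjusted p under 0.05. For camera, 1 of 10 splits, the real one, called as many as 15 lists, and the highest of the others called 12, in a split that called 0 genes with edgeR and 141 at an unadjusted p under 0.05. In both cases 10 splits are too few for a share under 0.05. The other splits mix the genotypes in unequal numbers, so they still carry part of the genotype difference. They therefore cannot show how many lists camera calls when nothing differs. In simulated counts, where genes varied independently, camera called 0 of 37 lists with no list changed and 1 with the length trend only. Real genes vary together, so the weight of the calls with the preset correlation stays uncertain, beside the 0 calls with an estimated correlation.

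Nuclear OXPHOS genes were higher in GOT1-/- cells, and short genes were higher in general. The values argue against the trend over the deposited gene lengths as the whole cause. After it was removed the list's median was 0.308, above all 10000 random lists matched on length and expression, whose median was 0.08. Removing length and GC content together left 0.315. The lengths of the transcripts present in these cells were not measured, so a trend over those lengths was not tested. The random lists drew each gene separately, while the estimated correlation between genes of this list was 0.367. Their spread is therefore too narrow for genes that vary together. Members over the list's median length gave a corrected median of 0.32, with 23 of 34 called higher and 2 lower. The corrected medians were below the uncorrected one of 0.47, so a part of the rise that goes with length is not excluded. Another property shared by these genes, RNA quality, and an effect of GOT1 loss on these transcripts all stay open, the last as an untested hypothesis.

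Mitochondrially encoded genes were lower although they are among the shortest, so that the length trend predicts the opposite direction. Their median log2 fold change was -0.75 with the length correction and -0.525 with length and GC content removed together, below all 10000 matched random lists in both cases. Here too the random lists drew each gene separately, while the estimated correlation between the mitochondrially encoded genes was 0.174. A lower yield of these transcripts in poly-A selection, a lower content of mitochondrial RNA, and an effect of GOT1 loss stay open and were not tested.

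Of 10 macrophage, monocyte and neutrophil markers 7 rose and Cd68 fell (adjusted p = 0.348 with an estimated correlation), while Mrc1, Cxcr2 and Ly6g, which myeloid cells can express, also fell; a trace of other cells may be the source of those that rose, although the sort for naive CD4 T cells should remove them. Lists of 12 neutrophil, 11 macrophage and 8 mast cell and basophil genes, written before their values were seen, gave ratios of summed CPM in GOT1-/- to WT of 0.678, 0.958 and 1.29, which met the limits set in advance against the first pair and the prediction for the last. Those sums decide nothing in either direction, because Cxcr2, Ctss and Cyp11a1 held 92.5, 97.8 and 92.2% of the WT counts of their lists, so that each sum followed 1 gene. Without those genes, a step chosen after the values were seen, the sums were higher in every GOT1-/- library for neutrophils (1.48 ± 0.37 against 3.07 ± 0.562 CPM, SD, n = 3, ratio 2.08) and for mast cells and basophils (5.92 ± 0.616 against 10.2 ± 0.134 CPM, ratio 1.71), the latter through Prss34 and Gata2 while Hdc and Slc18a2 were not called, but not for macrophages (ratio 1.11), and Mmp9 and Mrc1 still held 54.1 and 58% of the WT counts of the neutrophil and macrophage sums. A trace of neutrophils stays open, since few counts remain (21 to 38 per WT and 43 to 73 per GOT1-/- library). Lcn2 and Mmp9, which hold most of them, were not called (adjusted p = 0.23 and 0.0665). The other 9 genes had at most 9 counts in any library. Outside these sums, S100a9 had 1, 0 and 2 counts in WT replicates 1 to 3 and 37, 49 and 21 in GOT1-/- replicates 1 to 3. The neutrophil granule protein gene Ngp had 2, 3 and 2 counts in WT and 27, 35 and 7 in GOT1-/- libraries. Ngp was chosen after its values were seen, as near absent in WT, so its rise was set by that choice. Traces of the other cell types and expression by the T cells themselves stay open as well.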
